A study of Homo sapiens with 72 samples.

How the data were processed

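RNA of neutrophils and PBMC from patients with juvenile idiopathic arthritis and from healthy controls was measured on Affymetrix HG-U133 Plus 2.0 arrays, 1 array per sample and 72 arrays in all. The deposited values are probe set intensity on a linear scale, made by the authors with Affymetrix Expression Console and RMA per the labels, for which no version or setting is stated. The values ranged from 5.01 to 30790, and array medians from 20.5 to 41.8. Mean intensity was 179 to 198 on neutrophil arrays and 225 to 245 on PBMC arrays, apart from 1 PBMC array at 117, so levels were not compared between the cell types, only differences from controls.

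Intensities were taken to log2 without a further normalization. Of 54675 probe sets, 41097 carried 1 gene symbol, 1801 carried several and 11721 carried none, and 62 control probe sets were left out. Probe sets of chromosome Y, XIST and TSIX (99) were left out of every step to protect the donors. Each of 19738 genes took its single-symbol probe set of highest mean over the 72 arrays. A gene was tested in a cell type when its log2 value was above 5 on at least 8 arrays of that cell type, which left 10790 genes in neutrophils and 13102 in PBMC, and 13289 in either for the comparison between cell types.

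Each cell type was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings, 3 groups in one fit), and 3 contrasts were tested, polyarticular minus control, pauciarticular minus control and polyarticular minus pauciarticular. Tests were 2-sided, with Benjamini-Hochberg adjustment over all genes tested in the cell type and a threshold of 0.05. Errors of differences are standard errors from limma. The neutrophil minus PBMC difference of each disease difference was tested in 1 limma fit of all 72 arrays. The replicate numbers in the labels were not used as pairs. Same-numbered samples were compared only between disease groups within a cell type. Whether the same number in neutrophils and PBMC stands for the same person was not checked. The fit of all 72 arrays treated arrays as independent, though neutrophils and PBMC may share persons. Genes changed in the same direction in both diseases were counted, and the effect of the shared controls was examined with 100 simulations and with 100 divisions of the controls. Gene lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, and members were also adjusted over the list alone. The 35 lists cover interferon, NF-kB, immediate early, inflammasome, toll-like receptor, granule, respiratory burst, Fc and complement receptor, S100, chemokine, antigen presentation, T helper, glucocorticoid, folate, heat shock, hypoxia, cell cycle, ribosomal, oxidative phosphorylation, proteasome and apoptosis genes, and markers of 11 blood cell types. The median, mean and test of a list differed in sign for 8, 10 and 2 lists in the 3 neutrophil comparisons and 8, 3 and 9 in the 3 PBMC comparisons, none of them called. Tables were read with data.table (version 1.17.8), and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

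The groups, the tests, the lists, the first 10 alternatives, the camera setting and the rule for named genes were chosen before the data were examined. The rule names, in each comparison, the 10 genes with the largest positive and the 10 with the largest negative difference among those that passed, the 5 of smallest p where none passed, the 4 list members with the largest absolute difference in each list the text describes, and the 10 higher and 10 lower shared genes with the largest smaller difference. PSMB8, MYL9 and the other named genes follow this rule.

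The alternatives were no filter and a stricter filter (log2 above 6), the mean of a gene's probe sets, every probe set on its own, quantile normalization again, subtraction of the array median, eBayes with trend and robust, array weights, the replicate number as a block, and only the groups compared. After the arrays were seen, 6 settings were added, which are leaving out 1 divergent PBMC array (median correlation with its group under 0.8), spike-in class as a block, a coarser class as a block, only arrays of the controls' classes, the ACTB 3′ minus 5′ difference as a covariate, and leaving out controls of high ACTB difference (above 0.3 in PBMC and 0.6 in neutrophils). The block, covariate and left-out-control settings also leave out the divergent array. The classes part the arrays of a cell type at gaps over 0.5 in the mean log2 signal of the bacterial spike-in probe sets. An array left alone by this rule joins the class of its nearest neighbour. In neutrophils the low class ends at 5.996 and the middle class begins at 6.56, a gap little over the limit. The coarser classes part at gaps over 2, which gives 1 class in PBMC. Both groupings were looked at and both are reported. The limits were set after the arrays were seen.

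The code was tested on simulated data with known differences. Noise was drawn independently for each gene, without spike-in classes or RNA integrity differences, so the shares found need not hold for the real arrays. A difference of 1 (log2) was found for 90.2% of genes in polyarticular and 86.9% in pauciarticular neutrophils, and for 93.8% and 87.7% in PBMC, where 13 polyarticular arrays were used. A difference of 0.5 was found for 50.0% and 40.6% in neutrophils and 82.8% and 73.4% in PBMC, and a difference of 0.25 for 14.9% and 4.48% in neutrophils and 41.8% and 25.4% in PBMC, with 3.53% to 10.4% of the calls against controls false. In a simulation added after the results were seen, with genes changed in polyarticular arrays only, polyarticular minus pauciarticular differences of 1, 0.5 and 0.25 were found for 87.7%, 47.8% and 7.58% of genes in neutrophils and 95.3%, 74.6% and 17.9% in PBMC. The number of arrays limits the precision of each value, and arrays give no read depth.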

Results

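RNA of neutrophils and of peripheral blood mononuclear cells (PBMC) was measured on 72 expression arrays, 1 array per sample, from patients with juvenile idiopathic arthritis and from healthy controls. Juvenile idiopathic arthritis is a chronic inflammation of the joints that begins in childhood. The labels divide the patients into a polyarticular form, in which many joints are affected, and a pauciarticular form, in which few are. The neutrophil arrays comprised 14 polyarticular, 8 pauciarticular and 13 control samples, and the PBMC arrays comprised 14 polyarticular, 8 pauciarticular and 15 control samples. Each array carried 54675 probe sets, from which 19738 genes received a value, and 10790 genes in neutrophils and 13102 genes in PBMC passed the filter on low signal. Median intensity per array ranged from 20.5 to 22.1 in polyarticular neutrophils and from 37.4 to 41.8 in polyarticular PBMC. Arrays give no read depth, and the number of arrays limits the precision of each value. The p-values set each group difference against the spread between samples within groups, which also holds technical differences between arrays.

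The arrays also differed in technical measures, and these differences were spread unevenly over the groups. Bacterial RNAs that are added before labelling separated the arrays of each cell type into 3 classes by signal, and the controls did not occupy all of them. A class without controls gives no direct comparison with controls, so a fit blocked by class leaves fewer arrays for it. The labels name no batch, and whether these classes are labelling batches is not known. In neutrophils all 13 controls were in the middle class (mean log2 signal from 6.56 to 7.25), with 5 polyarticular and 2 pauciarticular samples. The low class held 6 polyarticular samples and the high class held 3 polyarticular and 6 pauciarticular samples. In PBMC the low class held 7 polyarticular and 6 pauciarticular samples and no control, the middle class 3 controls, 2 polyarticular and 1 pauciarticular sample, and the high class 12 controls, 5 polyarticular and 1 pauciarticular sample. The difference between the 3′ and 5′ probe sets of ACTB, a measure of RNA integrity, was between 0.36 and 0.84 (log2) in 7 of the 15 PBMC controls and between 0.067 and 0.17 in the 8 pauciarticular PBMC samples. In neutrophils 6 of the 13 controls had values between 0.78 and 1.39. Values were also high in 4 of the 8 pauciarticular samples (0.61 to 0.81) and in 1 of the 14 polyarticular samples. In addition, 1 polyarticular PBMC array stood apart, with a median correlation of 0.602 to its group, an ACTB difference of 4.60 and a mean intensity of 117, against at least 225 on the other PBMC arrays. Without it, the first principal component in PBMC (20.8% of variance) had an r2 of 0.59 with the ACTB difference and 0.52 with disease group. In neutrophils the first (25.9%) had 0.0052 with disease group. The second (15.7%) had 0.40 with spike-in class and 0.23 with disease group.

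**Figure D1:**
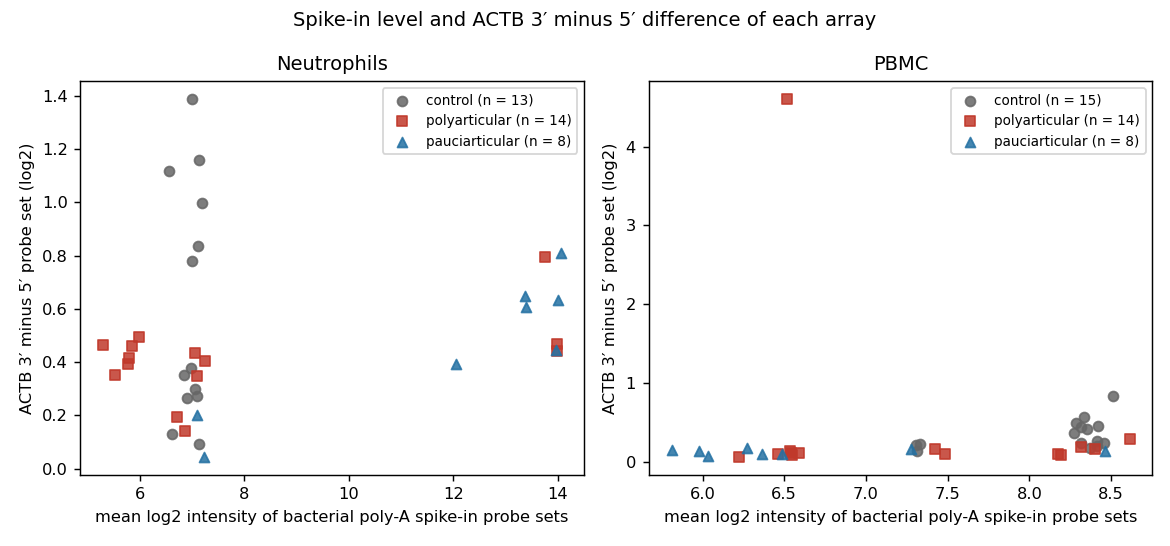
Each point is 1 array of neutrophils (left) or PBMC (right), with the mean log2 intensity of the bacterial spike-in probe sets on the x axis and the log2 difference between the 3′ and 5′ ACTB probe sets on the y axis. The 13 neutrophil controls occupy 1 spike-in class between 6.56 and 7.25, and 1 polyarticular PBMC array lies at an ACTB difference of 4.60.

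The first comparison asked which genes differ in neutrophils between polyarticular disease and health. The differences were mostly decreases: 444 genes were lower and 26 were higher in the 14 polyarticular than in the 13 control samples (limma, 470 of 10790 genes). Without the 6 controls of high ACTB difference they were 819 lower and 292 higher. The smallest adjusted p values were those of decreases in HOMER1 (-0.77 ± 0.10, limma adjusted p = 4.22e-05) and LCOR (-0.79 ± 0.11, limma adjusted p = 5.31e-05). Among the 10 largest decreases the smallest adjusted p values were those of SCLT1 (log2 difference -1.002 ± 0.16 SE, limma adjusted p = 0.000522) and HOOK3, which encodes a microtubule adaptor (-0.87 ± 0.13, limma adjusted p = 0.000461), and both genes were below the control mean in 14 of 14 polyarticular samples. SLPI, a secreted inhibitor of neutrophil elastase (-1.09 ± 0.31, limma adjusted p = 0.0354), the chemokine gene CXCL6 (-0.91 ± 0.24, limma adjusted p = 0.0264) and the transcription factor gene RUNX2 (-0.87 ± 0.18, limma adjusted p = 0.00578) also fell. LINC00189, MDM1, GRAMD1C, ACP3 and THAP9-AS1 fell by 1.09, 1.06, 1.03, 0.97 and 0.92 on the log2 scale. The increases were led by GUSBP14 (0.99 ± 0.30), which rose on 1 of its 2 probe sets, and by CNIH4 (0.82 ± 0.20, limma adjusted p = 0.0141). They included MAP2K6, a kinase upstream of p38 (0.77 ± 0.22), the coagulation factor gene F5 (0.70 ± 0.21) and the stress response gene GADD45B (0.61 ± 0.13, limma adjusted p = 0.00757, higher than the control mean in 14 of 14 samples). APMAP, UBN1, KREMEN1, ID3 and SLC71A3P rose by 0.71, 0.68, 0.62, 0.56 and 0.48.

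**Figure D2:**
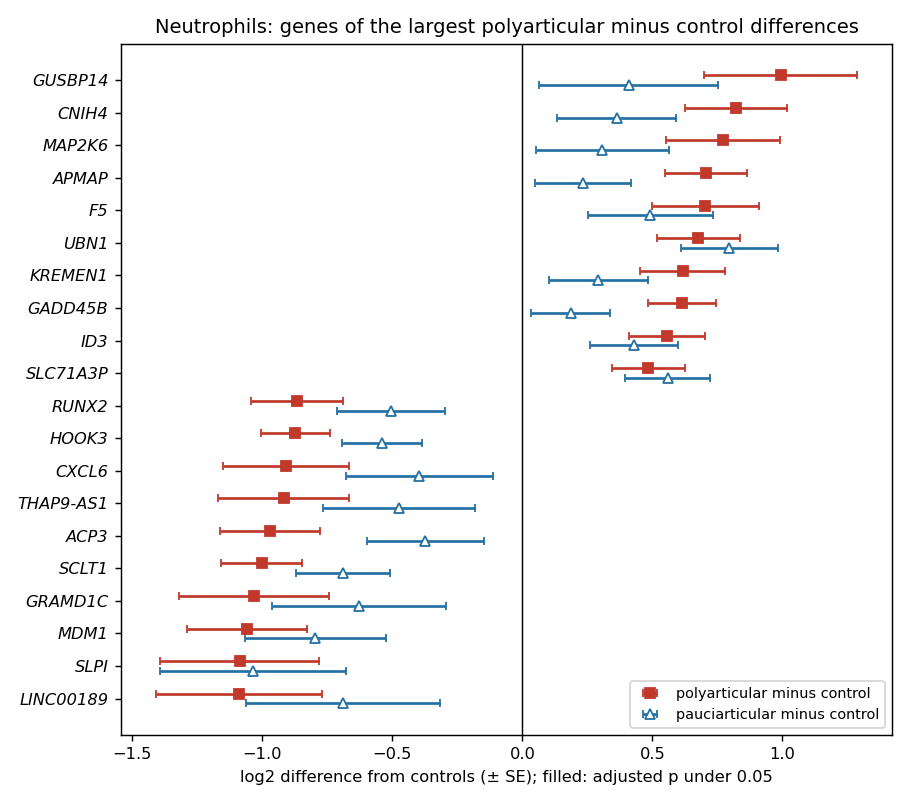
Log2 differences from the 13 controls (x axis, ± SE) of 20 neutrophil genes, the 10 largest increases and 10 largest decreases among genes that passed in polyarticular disease. Squares are the 14 polyarticular and triangles the 8 pauciarticular samples, filled where the limma adjusted p is under 0.05. None of the 20 pauciarticular differences, which use the same 13 controls, is filled.

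Among the 35 gene lists fixed before the data were examined, 6 were higher in polyarticular neutrophils by limma's camera test. The 28 type I interferon response genes had a median difference of 0.39 (camera adjusted p = 0.00295), with OAS2 at 0.87 ± 0.74 and PLSCR1 at 0.79 ± 0.29, but none passed the test alone. Of 20 interferon gamma response genes (median 0.18, camera adjusted p = 0.0173), 2 rose, also when adjusted over the list alone, and 1 of them was PSMB8, an immunoproteasome subunit (0.40 ± 0.11, limma adjusted p = 0.0278). Ribosomal protein genes (36 genes, median 0.30, camera adjusted p = 7.82e-07) held no member that passed, and RPL3 stood at 0.63 ± 0.31. Markers of other blood cells shifted in the same direction, with medians of 0.48 for 22 T cell markers (CD3G 1.01 ± 0.33), 0.67 for 16 platelet markers (PF4 1.26 ± 0.51) and 0.63 for 18 erythroid markers (ALAS2 1.43 ± 0.48), and camera adjusted p = 3.45e-07, 3.73e-07 and 1.73e-06. No member of these 3 lists passed alone, and 0 passed when adjusted over the list alone. All 6 calls were lost with an estimated correlation between genes (adjusted p = 0.878 with an estimated correlation for type I interferon and adjusted p = 0.865 for the others). The remaining 29 lists had medians from -0.31 to 0.24 and camera adjusted p from 0.0775 to 0.999.

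The number of changed genes depended on how the spike-in classes were treated: with class as a block 15 genes changed, and with 2 coarser classes 373. The block by class leaves mainly the 5 polyarticular samples of the middle class to set against controls. A fall from fewer usable arrays and a fall from removing a class effect cannot be told apart. Among the 5 polyarticular and 13 control samples of the middle class limma called 1 gene (1067 at an unadjusted p under 0.05), the median signed difference of the 470 genes, which were chosen on arrays that include these, was 0.36 against 0.44 over all arrays, and the erythroid and platelet medians were -0.0030 and 0.32.

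In neutrophils of pauciarticular disease, 22 genes differed from the 13 controls (limma), with 19 lower and 3 higher in the 8 patients. The smallest adjusted p was that of a decrease in HM13, which encodes signal peptide peptidase (log2 difference -0.69 ± 0.12, limma adjusted p = 0.0217, lower than the control mean in 8 of 8 samples). NUMB, an inhibitor of Notch signalling (-0.71 ± 0.14), the RNA helicase gene DDX6 (-0.73 ± 0.15, on 1 of 2 probe sets), the histone deubiquitinase gene MYSM1 (-0.71 ± 0.16) and the kinase gene MAP2K2 (-0.69 ± 0.16) fell as well. FCHSD1, PHKG2, FAM13A-AS1, UBLCP1 and SAMD8 fell by 0.72, 0.65, 0.61, 0.59 and 0.58. The 3 increases were GTF2IP12 (0.97 ± 0.22), PNISR (0.64 ± 0.14, on 3 of 6 probe sets) and the chromatin remodelling gene BPTF (0.58 ± 0.12, on 1 of 3 probe sets), and BPTF stood at -0.012 when its probe sets were averaged.

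Camera called 8 lists higher in pauciarticular neutrophils, in none of which a member passed over all genes. Platelet markers had the largest median (0.71 over 16 genes, camera adjusted p = 5.04e-12), and 3 of them rose when adjusted over the list alone. PPBP and PF4, which encode platelet chemokines, stood at 1.76 ± 0.73 and 1.66 ± 0.59. Erythroid markers (median 0.42, camera adjusted p = 5.61e-05), 13 MHC class II presentation genes (0.31, camera adjusted p = 0.00343), type I interferon response genes (0.25, camera adjusted p = 0.00756) and 18 monocyte markers (0.25, camera adjusted p = 0.0172) followed. T cell markers (0.22, camera adjusted p = 0.00343), ribosomal protein genes (0.21, camera adjusted p = 4.98e-05) and 17 B cell markers (0.17, camera adjusted p = 0.0276) completed the 8. For these 7 lists 0 members passed when adjusted over the list alone. All 8 calls were lost with an estimated correlation (adjusted p = 0.961 with an estimated correlation). The type I interferon call did not hold without either of 2 of the 8 patients' arrays in turn (median from -0.15 to 0.44, camera adjusted p up to 0.996), the B cell call without 4 of them and the monocyte call without 1. The other 27 lists had medians from -0.15 to 0.17 and camera adjusted p from 0.0969 to 0.977.

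No gene changed in pauciarticular neutrophils with spike-in class as a block in limma (284 at an unadjusted p under 0.05), and leaving out single patients' arrays gave counts from 0 to 222. Only 2 pauciarticular samples shared a class with controls, so the block also left few arrays to compare. Inside the middle class, with 2 pauciarticular and 13 control samples, limma called 0 genes (164 at an unadjusted p under 0.05), the median signed difference of the 22 genes was 0.22 against 0.59 over all arrays, and the medians of the type I interferon, T cell, B cell, monocyte, ribosomal and erythroid lists were negative.

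Polyarticular and pauciarticular neutrophils were then compared with each other. Of 10790 genes 0 passed in limma, and 600 had an unadjusted p under 0.05. The 5 genes of smallest p, none of which passed (limma adjusted p = 0.804), were CCDC57 (log2 difference 0.32 ± 0.07), LOC283045 (-0.40 ± 0.10), ANGPT1, an angiopoietin carried by platelets (-1.40 ± 0.36), ATP13A2 (0.44 ± 0.12) and RBM4 (-0.63 ± 0.17). None of the 35 lists was called, with medians from -0.24 to 0.29 and camera adjusted p from 0.0628 to 0.915. Camera did call 10 lists with spike-in class as a block, 9 with the coarser classes, 12 on arrays of the controls' classes (5 against 2) and 7 with every probe set on its own. It called 2 with the replicate block, 1 with the stricter filter and 1 with only the groups compared, and with an estimated correlation 0 under every setting. With class as a block they included type I interferon response genes (median 0.76, adjusted p = 0.677 with an estimated correlation) and T cell markers (0.42, adjusted p = 0.677 with an estimated correlation). For single genes limma called 0 under every alternative setting tried. On simulated arrays of these group sizes limma found 87.7% of the genes that differed by 1 (log2) between the forms, 47.8% at 0.5 and 7.58% at 0.25. Those arrays had noise independent between genes and no spike-in classes, so these shares need not hold for the real arrays.

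In PBMC of polyarticular disease the changed genes included platelet and erythroid genes, which were higher than in controls, and genes of cytotoxic lymphocytes, which were lower. Of the markers tested, 7 of 21 for platelets and 7 of 20 for erythroid cells rose and 8 of 22 for NK and cytotoxic cells fell. The 3 list calls were lost (adjusted p = 0.803, 0.803 and 0.92 with an estimated correlation). MYL9, a myosin light chain gene (log2 difference 2.16 ± 0.39, 4.48-fold, on 1 of 2 probe sets), the platelet integrin genes ITGB3 (1.64 ± 0.37, 3.11-fold) and ITGA2B (1.27 ± 0.33), and the megakaryocyte receptor gene MPIG6B (1.63 ± 0.27, limma adjusted p = 0.00134, higher than the control mean in 14 of 14 samples) rose in the 14 patients against 15 controls. ALAS2, the erythroid enzyme of heme synthesis (1.84 ± 0.44, limma adjusted p = 0.0159), and TRIM58 (1.31 ± 0.26) rose with them, as did TGFB1I1, TMEM158, WASF3 and PARVB (1.58, 1.44, 1.27 and 1.19). The 10 largest decreases included the killer cell receptor genes KLRC3 (-1.09 ± 0.29), KLRB1 (-0.98 ± 0.22), KLRF1 (-0.97 ± 0.25) and KLRD1 (-0.93 ± 0.23) and GZMK, a granzyme (-1.02 ± 0.25, limma adjusted p = 0.0173). The other 5 were A2M-AS1, LRRN3, AKR1C3, KLF3-AS1 and MYBL1, which fell by 1.04, 1.00, 0.98, 0.91 and 0.90. In all, limma called 842 of 13102 genes, 367 higher and 475 lower, and requantile-normalised values gave 568 higher and 260 lower.

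**Figure D3:**
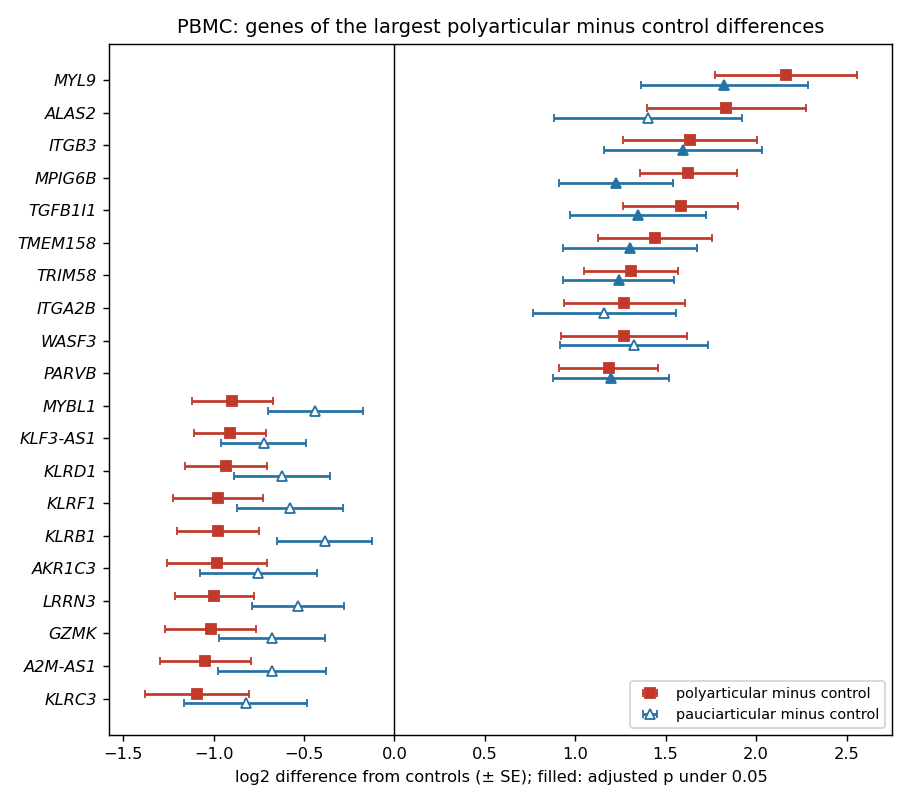
Log2 differences from the 15 controls (x axis, ± SE) of 20 PBMC genes, the 10 largest increases and 10 largest decreases among genes that passed in polyarticular disease. Squares are the 14 polyarticular and triangles the 8 pauciarticular samples, filled where the limma adjusted p is under 0.05. MYL9 is at 2.16 and 1.82, and KLRD1 is at -0.93 and -0.62 without passing in pauciarticular disease.

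Camera called 10 lists in this comparison. Of 21 platelet markers 7 rose over all genes and 15 when adjusted over the list alone (median 0.81, camera adjusted p = 1.22e-10), among them ALOX12 (1.05 ± 0.32, limma adjusted p = 0.043). Of 20 erythroid markers 7 rose over all genes and 15 when adjusted over the list alone (median 1.00, camera adjusted p = 2.29e-11). SELENBP1 and HBD of that list stood at 1.34 ± 0.43 and 1.31 ± 0.58 without passing. Of 22 NK and cytotoxic cell markers 8 fell, and 16 fell and 1 rose when adjusted over the list alone (median -0.77, camera adjusted p = 1.01e-06). Of 15 specific and gelatinase granule genes 2 rose, also when adjusted over the list alone (median 0.57, camera adjusted p = 3.60e-05), and 1 of them was LCN2, a siderophore-binding protein of neutrophil granules (0.73 ± 0.23, limma adjusted p = 0.0495). Mature neutrophil markers (17 genes, median 0.57, camera adjusted p = 0.000137, KCNJ15 0.92 ± 0.40), azurophil granule genes (8 genes, median 0.39, camera adjusted p = 0.0126, RNASE2 0.55 ± 0.24) and B cell markers (19 genes, median 0.18, camera adjusted p = 0.00179, CD79A 0.57 ± 0.28) were called higher with 0 members passing, also when adjusted over the list alone. Without the controls of high ACTB difference the B cell median was -0.063 and its call did not hold, with CD79A at -0.015. Ribosomal protein genes (36 genes, 2 lower, 3 when adjusted over the list alone, median -0.46, camera adjusted p = 6.15e-05), oxidative phosphorylation genes (37 genes, 4 lower, 5 when adjusted over the list alone, median -0.33, camera adjusted p = 2.70e-05) and proteasome genes (23 genes, 0 passing either way, median -0.26, camera adjusted p = 0.00179) were called lower. By fry, which tests whether a list moves on balance one way, only the erythroid list passed (adjusted p = 0.0398). All 10 camera calls were lost with an estimated correlation (adjusted p = 0.803 with an estimated correlation for the platelet, erythroid and specific granule lists, 0.92 for the NK, mature neutrophil and azurophil lists, and 0.991 for the other 4). The other 25 lists had medians from -0.30 to 0.11 and camera adjusted p from 0.0824 to 0.977.

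**Figure D4:**
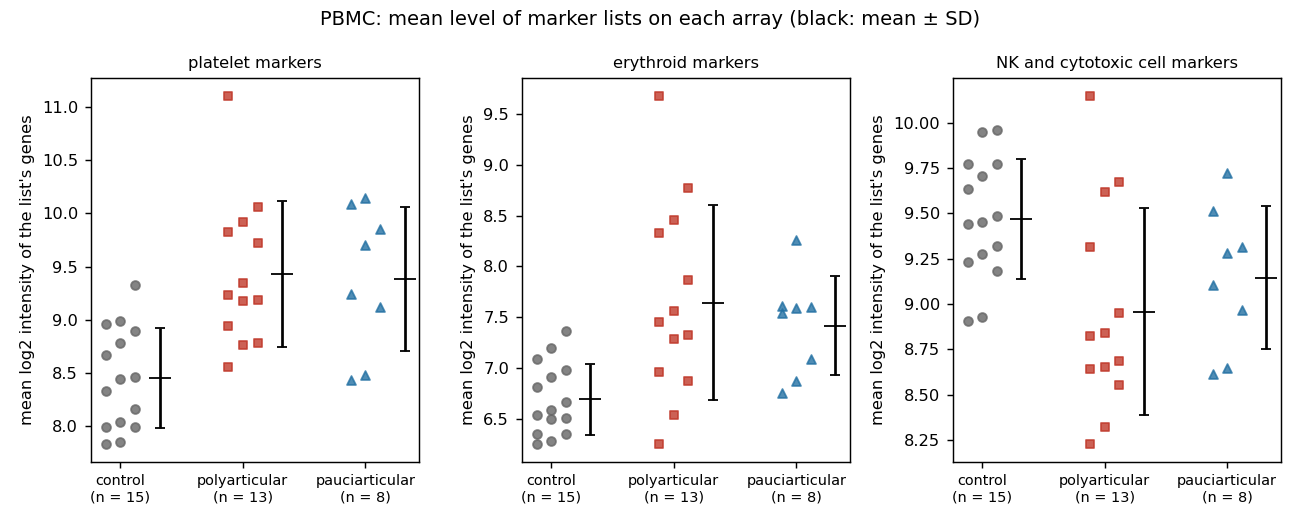
Each point is the mean log2 intensity of a marker list on 1 PBMC array, with the polyarticular array that stood apart left out, and black marks give the group mean ± SD. Mean platelet marker level was 8.45 in 15 controls, 9.43 in 13 polyarticular and 9.38 in 8 pauciarticular samples, and mean NK marker level was 9.47, 8.96 and 9.15.

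Without the array that stood apart 2035 genes changed and the medians of the ribosomal, oxidative phosphorylation and proteasome lists moved to -0.087, -0.15 and -0.11. Over the called lists of all comparisons, 5 calls were lost without it and 1 turned direction, some of them in comparisons with controls. The block of spike-in class gave 390 changed genes, with the ACTB difference as a covariate limma called 0 (1947 at an unadjusted p under 0.05), and inside the classes limma called 0 of 13102 genes in 5 polyarticular against 12 control samples (2544 at an unadjusted p under 0.05) and 0 in 2 against 3 (948), with platelet medians of 0.55 and 1.12, erythroid medians of 0.85 and -0.14 and NK medians of -0.30 and -0.95.

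In pauciarticular PBMC 4 of 21 platelet and 4 of 20 erythroid markers rose against the 15 controls, and both list calls were lost (adjusted p = 0.955 with an estimated correlation). ALAS2 (1.40 ± 0.52) and ITGA2B did not pass (limma adjusted p = 0.101 and 0.0727). MYL9 (log2 difference 1.82 ± 0.46, 3.54-fold, limma adjusted p = 0.021, on 1 of 2 probe sets), ITGB3 (1.59 ± 0.44, higher than the control mean in 8 of 8 samples), TRIM58 (1.24 ± 0.31) and MPIG6B (1.22 ± 0.32) rose in the 8 patients. DDX11L2 (1.67 ± 0.39), the exchanger gene SLC24A3 (1.41 ± 0.42) and CLU, which encodes clusterin (1.23 ± 0.35), rose too, as did TGFB1I1, TMEM158 and PARVB (1.35, 1.30 and 1.20). Decreases were smaller, with LOC145474 at -1.18 ± 0.25 (limma adjusted p = 0.00744), the phosphatase gene CDC14A at -0.72 ± 0.21 and ZHX1 at -0.69 ± 0.15. VTI1A, CCZ1B, XKR6, LCORL, DDHD1-DT, LRRC69 and THOC2 fell by 0.68, 0.67, 0.67, 0.65, 0.65, 0.60 and 0.59. In all, limma called 658 of 13102 genes, 422 higher and 236 lower, and requantile-normalised values gave 316 higher and 56 lower. The balance turned without the polyarticular array that stood apart (1047 higher and 1146 lower), with only the groups compared (1116 and 1331), with array weights (1403 and 1529), with every probe set on its own (1202 and 1477) and without the controls of high ACTB difference (936 and 1057).

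Of 21 platelet markers 4 rose over all genes and 16 when adjusted over the list alone (median 0.89, camera adjusted p = 1.11e-09). Of 20 erythroid markers 4 rose, and 7 when adjusted over the list alone (median 0.90, camera adjusted p = 5.49e-06), including DMTN (1.10 ± 0.29) and GMPR (1.07 ± 0.32). Among 15 specific and gelatinase granule genes LCN2 rose (1.08 ± 0.27, limma adjusted p = 0.0205), 4 rose when adjusted over the list alone, and CEACAM8 and LTF, which encodes lactoferrin, stood at 1.55 ± 0.54 and 1.53 ± 0.58 (median 0.53, camera adjusted p = 8.73e-05). Azurophil granule genes (median 0.50, camera adjusted p = 0.0148, MS4A3 0.90 ± 0.37) were called with 0 members passing either over all genes or when adjusted over the list alone. Of 9 basophil and mast cell markers 1 rose, and 3 when adjusted over the list alone (median 0.45, camera adjusted p = 0.0108, CPA3 0.89 ± 0.38). Oxidative phosphorylation genes (median -0.15, with UQCRB lower at -0.32 ± 0.08, limma adjusted p = 0.0203, and 1 lower when adjusted over the list alone), proteasome genes (median -0.17) and NK and cytotoxic markers (median -0.41, KLRD1 -0.62 ± 0.27), the last 2 with 0 members passing either way, were called lower at camera adjusted p = 0.0308. With an estimated correlation all 8 calls were lost (adjusted p = 0.955 with an estimated correlation for the platelet, erythroid, specific granule and basophil lists and 0.9753 for the other 4). The other 27 lists had medians from -0.19 to 0.29 and camera adjusted p from 0.102 to 0.983.

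Without the polyarticular array that stood apart, which shares the fit, 2193 genes changed, and limma called 0 with spike-in class as a block (1378 at an unadjusted p under 0.05). Only 2 pauciarticular samples shared a class with controls, so a loss of usable arrays cannot be told apart from a class effect there. The 2 pauciarticular and 15 control samples of the controls' classes gave 56 genes, all higher, and the ACTB covariate gave 146, while each single class held only 1 pauciarticular beside control samples, too few for a value. On those 2 and 15 samples camera called 1 list with an estimated correlation.

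Between polyarticular and pauciarticular PBMC limma called 0 of 13102 genes, and 447 had an unadjusted p under 0.05. The 5 genes of smallest p, none of which passed (limma adjusted p = 0.97), were ACTG1P17 (log2 difference -0.26 ± 0.06), LINC00491 (-0.48 ± 0.12), LLPH (0.30 ± 0.08), LOC338963 (-0.30 ± 0.08) and IL17RB, a receptor for interleukin 25 (-0.34 ± 0.09). Camera called 11 lists, in which 0 members passed over all genes or when adjusted over the list alone. Higher in polyarticular disease were 23 cell cycle genes (median 0.33, camera adjusted p = 1.27e-10, ZWINT 0.60 ± 0.24), mature neutrophil markers (0.28, camera adjusted p = 0.013), B cell markers (0.13, camera adjusted p = 0.00567) and erythroid markers (0.086, camera adjusted p = 0.0277). Lower were ribosomal protein genes (-0.39, camera adjusted p = 0.000655), MHC class II genes (-0.37, camera adjusted p = 0.00361), monocyte markers (-0.36, camera adjusted p = 0.000554, CPVL -0.57 ± 0.26) and NK and cytotoxic markers (-0.31, camera adjusted p = 0.000744, XCL1 -0.60 ± 0.23). Basophil and mast cell markers (-0.28, camera adjusted p = 0.000956, FCER1A -0.97 ± 0.43), 11 dendritic cell markers (-0.19, camera adjusted p = 0.0112) and oxidative phosphorylation genes (-0.15, camera adjusted p = 0.0277) were lower as well. All 11 calls were lost with an estimated correlation (adjusted p = 0.632 with an estimated correlation for the cell cycle, dendritic and basophil lists and 0.978 for the others). On arrays of the controls' classes alone (7 against 2) camera called 3 lists with an estimated correlation. With the replicate number as a block camera called 4 lists. The other 24 lists of the main fit had medians from -0.27 to 0.0079 and camera adjusted p from 0.146 to 0.984. Without the array that stood apart the oxidative phosphorylation median was 0.013, the ribosomal median -0.015, and the calls of the ribosomal, oxidative phosphorylation, mature neutrophil and erythroid lists did not hold. The MHC class II, monocyte and NK medians were then -0.11, -0.15 and -0.17, with their calls kept, but on arrays of the controls' classes alone the NK median was 0.094, with XCL1 at 0.10, and the MHC class II median -0.0037, with HLA-DQA1 at 0.48 and HLA-DPA1 at 0.71, and neither call held.

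Genes changed in both forms of the disease were counted next. In PBMC 285 genes changed in the same direction against the controls, 145 higher and 140 lower, where 11.8 and 8.56 would be shared if the calls were independent, and 0 changed in opposite directions. MYL9, ITGB3, TGFB1I1, TMEM158, TRIM58, MPIG6B, PARVB, CLU, DDX11L2 and GMPR were the 10 largest shared increases, with the smaller of the 2 differences between 1.07 and 1.82. CDC14A, LOC145474, XKR6, THOC2, ZNF331, DDX52, ABCA5, GOLGA4, GPATCH2L and VPS13B were the 10 largest shared decreases, for example ZNF331 (-0.64 ± 0.11 and -0.58 ± 0.13) and GOLGA4, a protein of the Golgi (-0.53 ± 0.10 and -0.58 ± 0.12). In neutrophils 15 genes were shared, all lower, against 0.782 under independence. They included NUMB (-0.65 ± 0.12 and -0.71 ± 0.14), FAM13A-AS1, HOMER1 (-0.77 ± 0.10 and -0.57 ± 0.12), SAMD8, LCOR, MYSM1, DDX6, PHKG2, SMARCA2, a chromatin remodelling ATPase (-0.46 ± 0.09 and -0.51 ± 0.10), and GNAQ. Because both comparisons use the same controls, the overlap was also computed with the controls divided between the comparisons, and the median count was then 6 in PBMC (at most 33) and 0 in neutrophils (at most 12) in 100 divisions. Dividing also left fewer controls per comparison, and the polyarticular and pauciarticular counts themselves fell to medians of 38.5 and 126 in PBMC and 39 and 0 in neutrophils, so the fall in shared genes is not due to separate controls alone. The correlation of the 2 sets of differences across genes, which are not independent replicates, was 0.801 in PBMC and 0.717 in neutrophils, and 0.654 and 0.368 with divided controls. In 100 simulations with no change in any group the shared controls alone gave a mean of 0.432 in PBMC (at most 0.782) and 0.424 in neutrophils (at most 0.748), so the neutrophil correlation lay within the simulated range. Blocked by spike-in class, 0 genes were shared in either cell type in limma (0 pauciarticular genes passed), and without the array that stood apart 1132 were shared in PBMC.

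The last comparison asked whether the difference from controls was itself different between neutrophils and PBMC. For polyarticular disease 31 of 13289 genes differed (limma, 11 with a higher and 20 with a lower difference in neutrophils). A gene was tested when it passed the filter on low signal in either cell type. MPIG6B, TGFB1I1, TMEM192, MAGOHB, GPAM, DRC2 and DDHD1-DT did not pass it in neutrophils, nor CXCL6 and GPX3 in PBMC, so that a change in that cell type could not be measured and their values set one cell type against signal near background. MPIG6B, which rose in PBMC, had a difference of differences of -1.53 ± 0.29 (limma adjusted p = 0.00701), and SLPI, at -1.09 in neutrophils and 0.38 in PBMC, had -1.47 ± 0.35. CLN6, a lysosomal disease gene, fell in neutrophils (-0.58) and rose in PBMC (0.44), with a difference of -1.03 ± 0.20 (limma adjusted p = 0.00701), and BCKDK, a kinase of branched-chain amino acid breakdown, did likewise (-0.44 and 0.42, difference -0.86 ± 0.17, limma adjusted p = 0.00865). TGFB1I1, CXCL6, ACP3, MDM1, GPX3 and PPP3R1 had differences between -1.47 and -0.96. In the other direction MIR181A2HG had 1.08 ± 0.25, PNISR 0.87 ± 0.20, APMAP 0.85 ± 0.19 and VPS13B 0.69 ± 0.17, followed by TGS1, PCED1B-AS1, TMEM192, MAGOHB, GPAM and DRC2 between 0.63 and 0.48. For pauciarticular disease 5 genes differed, VPS13B (0.93 ± 0.19), TGS1 (0.88 ± 0.18), DDHD1-DT (0.70 ± 0.15), PCED1B-AS1 (0.70 ± 0.15) and HM13 (-0.75 ± 0.16), each at a limma adjusted p of 0.0446. Blocking by spike-in class left 1 and 0 genes that differed in limma (1250 and 266 at an unadjusted p under 0.05), and without the array that stood apart 343 and 57. With the replicate number as a block 137 and 15 differed, and whether the cell types share persons was not checked.

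**Figure D5:**
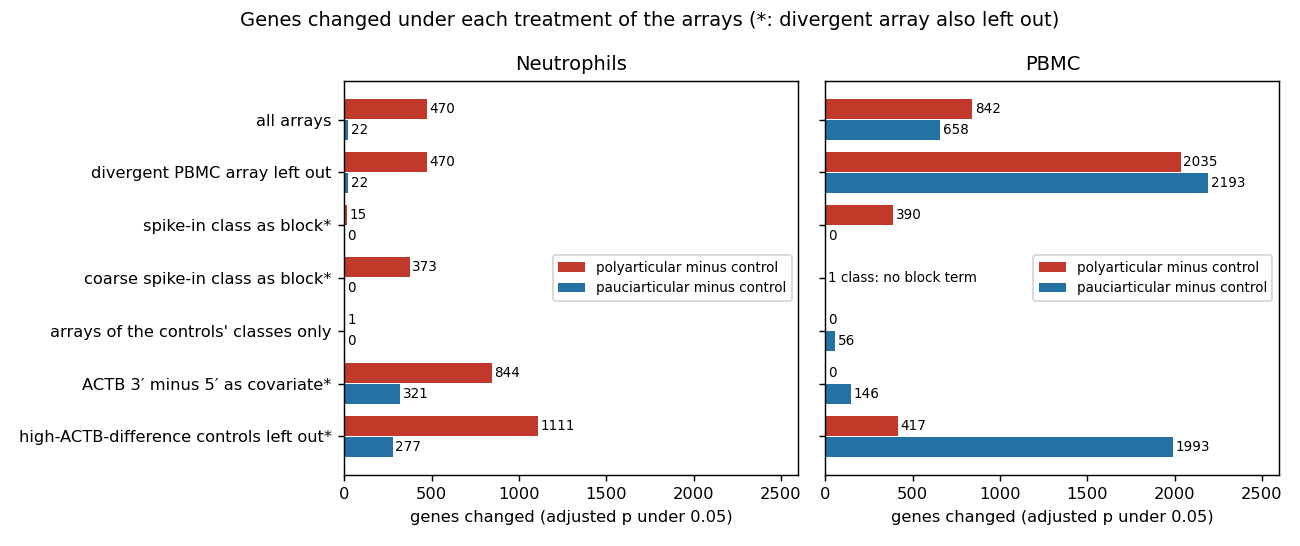
Bars give the number of genes with a limma adjusted p under 0.05 (x axis, from 0) against controls in neutrophils (left) and PBMC (right) under 7 treatments of the arrays, red for polyarticular and blue for pauciarticular disease. Polyarticular neutrophil counts run from 1 to 1111 and pauciarticular PBMC counts from 0 to 2193.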

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

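The tests of labelling batch and RNA integrity for the changed PBMC genes and for the lower neutrophil genes were chosen after the result was seen, and so was the further requirement that genes chosen on one part of the arrays hold on the others, which was added after first outcomes were known and left both PBMC tests of RNA integrity open. Reading the test of carried platelets and red cells as undecided was also settled after its value was known. The labels name no batch, so the spike-in classes stand in for labelling batches, which no label bears out, and a batch that the classes do not follow was not tested. The test of a lower neutrophil share, the tests of platelet and erythroid markers and the redrawn groups were written before.

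Among 159 values in the groups of 8 arrays, 19 had 1 array far from the others, where chance flags about 1 in 20 groups (7.95 of 159), and the values below give the gap to the nearest array over the whole range. In pauciarticular neutrophils these were USP18 (0.865), TUBB1 (0.717), PPBP (0.675), MYSM1 (0.669), OAS2 (0.644), RPS12 (0.609), PF4 (0.584), OAS3 (0.559), OAS1 (0.557), RPS23 (0.540), RPS21 (0.539) and RPL22 (0.532), and the mean of the type I interferon list (0.541). In pauciarticular PBMC they were FCRL2 (0.710), BPGM (0.635), ELANE (0.586), IL17RB (0.576), CR2 (0.534) and SELENBP1 (0.530). HLA genes were left out of this check after a first look.

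The difference from controls was itself different between the cell types for 31 genes in polyarticular and 5 in pauciarticular disease. Of the genes named here, MPIG6B, TGFB1I1, TMEM192, MAGOHB, GPAM, DRC2 and DDHD1-DT were under the filter on low signal in neutrophils, and CXCL6 and GPX3 in PBMC. In polyarticular disease the neutrophil minus PBMC values were 1.08 for MIR181A2HG, 0.87 for PNISR, 0.85 for APMAP, 0.69 for VPS13B, 0.63 for TGS1, 0.57 for PCED1B-AS1, 0.54 for TMEM192, 0.52 for MAGOHB, 0.50 for GPAM and 0.48 for DRC2. Negative values were -1.53 for MPIG6B, -1.47 for SLPI, -1.47 for TGFB1I1, -1.08 for CXCL6, -1.04 for ACP3, -1.03 for MDM1, -1.03 for CLN6, -1.0004 for GPX3, -0.96 for PPP3R1 and -0.86 for BCKDK. In pauciarticular disease they were 0.93 for VPS13B, 0.88 for TGS1, 0.70 for DDHD1-DT, 0.70 for PCED1B-AS1 and -0.75 for HM13.

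Probe sets without a gene symbol, which the main comparisons did not use, also changed when every probe set was tested on its own. In neutrophils 335 and 46 of 3385 changed in polyarticular and pauciarticular disease (9.90% and 1.36%, against 5.97% and 0.641% of single-symbol probe sets). In PBMC 743 and 710 of 4743 changed (15.7% and 15.0%, against 10.1% and 7.56%). The bacterial spike-in signal was above every control array on 11 patients' arrays in neutrophils and 1 in PBMC.

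The first pattern weighed was the genes changed in PBMC. In polyarticular disease the median signed difference on arrays of the controls' spike-in classes was 0.834 of the pooled one (95% bootstrap interval 0.678 to 0.967). On arrays not used to choose them, 500 genes held a median of 0.15 against 0.52 where they were chosen. The held median ranged from 0.025 to 0.20 over 100 random divisions of the controls. The patients' arrays stayed fixed, so this range does not measure the spread between patients. The 842 genes of the ratio were chosen on arrays that include those of the controls' classes, so a high ratio is partly built in. The held genes kept a median share of 0.294 of their difference. A batch that follows the spike-in classes therefore cannot be told apart. Without the controls of high ACTB difference the ratio was 0.691 (0.616 to 0.760), but chosen genes held -0.032, so RNA integrity cannot be told apart. In pauciarticular disease the ratio was 0.539 (0.390 to 0.733) for labelling, with 2 patients' arrays beside controls. For RNA integrity it was 0.951 (0.848 to 1.00), but chosen genes held -0.027. Without the controls of high ACTB difference 450 of the 658 genes still passed in limma and 658 kept their sign. With the ACTB covariate 107 of them passed. Neither labelling nor RNA integrity can be told apart from disease. Disease itself stays an untested explanation.

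The second pattern was the 444 genes lower in polyarticular neutrophils. A lower share of neutrophils is argued against as the whole cause only, since mature neutrophil markers moved by 0.0193 of the lower genes' median (-0.359 to 0.412). Markers of T cells, platelets and erythroid cells had higher medians in the same comparison, so a smaller change in share stays open. Without the controls of high ACTB difference the ratio was 1.03 (0.931 to 1.12), for genes chosen on arrays that include these. Genes chosen against the high-ACTB controls held 0.13 (0.035 to 0.21) against the other controls, and 0.53 where they were chosen. On these arrays the difference therefore does not come from the high-ACTB controls alone. The other controls had ACTB differences of 0.0935 to 0.38 and the polyarticular samples 0.14 to 0.80. RNA integrity was thus not balanced and cannot be told apart. Labelling batch cannot be told apart, because the ratio of 0.807 has an interval from 0.496 to 1.13 with 5 patients' arrays beside controls, and chosen genes held 0.18 (0.039 to 0.25) against 0.56. The ranges of the held values are over random divisions of the patients for RNA integrity and of the controls for labelling. The other group stayed fixed, so they do not measure its spread. Disease stays open as well.

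The third pattern was the platelet and erythroid markers in PBMC, and both ratios below are for polyarticular arrays only. In pauciarticular disease the mean platelet difference was 0.93 over all arrays and 1.67 with the 2 patients' arrays of the controls' classes. The mean erythroid difference was 0.72 and 0.54. Platelets and red cells carried into the mononuclear fraction cannot be told apart, since the mean correlation of residuals within each of the 2 lists, 0.669 on average, is expected of markers of one cell type whatever the cause of a group difference. Without the controls of high ACTB difference the ratio was 1.04 (0.841 to 1.19), so the difference does not come from those controls alone. The other 8 controls had ACTB differences of 0.14 to 0.26 and the 13 polyarticular arrays 0.059 to 0.29. RNA integrity was thus not balanced by leaving controls out. Neither RNA integrity nor labelling batch (ratio 0.632, 0.355 to 0.903) can be told apart. The carried cells were not measured apart from their RNA, and a higher number of platelets in the blood of patients stays open.

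Redrawn groups, 100 per comparison with the real one included, gave as many changed genes 2 times for polyarticular neutrophils (real 470, highest other 542), 1 time for pauciarticular neutrophils (22, 0), 1 time for polyarticular PBMC (842, 1) and 1 time for pauciarticular PBMC (658, 0). Each is a share under 0.05 for that count taken alone. The smallest share that 100 splits can give is 1 of 100, so they cannot exclude chance over all the counts read. For pauciarticular neutrophils, though, 2 of 100 simulations with no change in any group called 22 or more genes (at most 908), and leaving out single patients' arrays gave 0 to 222. Shared genes were as many 1 time in neutrophils (15, 0) and 1 time in PBMC (285, 0), and cell type differences 1 time in polyarticular disease (31, 4), again a share under 0.05 for each count taken alone.

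Pauciarticular cell type differences were as many 3 times (5, 271), a share under 0.05 for that count taken alone, but chance is not excluded over the 8 counts read, and the 5 became 0 in limma with trend and robust (1390 at an unadjusted p under 0.05) or with array medians subtracted (1349). The split with 271 genes called many times the real 5, and the reason was not tested. Between the diseases the real count was 0, so all 100 splits gave as many by construction in neutrophils (0, 21) and all 100 in PBMC (0, 66), which says nothing about chance. The neutrophil split with 542 genes had 3 high spike-in class arrays on one side and 0 on the other. In the same order it had 2 and 4 low class arrays and 4 and 3 arrays of high ACTB difference. The reason for its count was not tested, and the blocked count for the real groups was 15.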

How the results depend on the processing

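The settings that drop the array that stood apart, use the spike-in classes, restrict the arrays to the controls' classes or use ACTB were chosen after the data were seen, and the other 10 before. For the 269 results on named genes, the planned settings left 2436 values on the same side of the threshold, 170 lost and 53 gained a call, and 4 reversed, and the added settings left 1030, with 325 lost, 32 gained and 77 reversed. For 43 called lists the planned settings kept 397 calls, lost 74 and reversed 2, and the added ones kept 166, lost 45 and reversed 18. Of the 10 counts, 58 values stayed within 1.5 times under planned and 17 under added settings, and 42 and 39 did not. Counts between the diseases were 0 in limma under every setting run, with 600 neutrophil and 447 PBMC genes at an unadjusted p under 0.05 in the fit as reported. Where a value moved, the cause was not tested, except that every probe set on its own tests more features. Signal over background limits what arrays can show, and 51.5% of probe sets averaged at or under an intensity of 32.

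In counts, polyarticular and pauciarticular stand for the differences from controls. With no filter the pauciarticular neutrophil count was 7, the shared neutrophil count 5 and the polyarticular cell type difference 16. With the stricter filter these were 42 and 30 in neutrophils, with 414 for pauciarticular PBMC and 1 for the pauciarticular cell type difference. With the mean of a gene's probe sets neutrophil counts were 303, 2 and 2 shared. With every probe set on its own they were 1530, 176 and 118, PBMC counts were 3407, 2679 and 1458, and cell type differences 190 and 42. After quantile normalization polyarticular neutrophils had 224, pauciarticular PBMC 372, shared PBMC 183 and the pauciarticular cell type difference 9, and the share of lower genes went from 56.4% to 31.4% in polyarticular PBMC and from 35.9% to 15.1% in pauciarticular PBMC. With array medians subtracted cell type differences were 18 and 0 (1349 at an unadjusted p under 0.05 in limma), and with trend and robust the second was 0 (1390). With array weights pauciarticular neutrophils had 485, shared neutrophils 189, PBMC 1497, 2932 and 1063 shared, and cell type differences 126 and 223. With only the groups compared neutrophils had 13 and 9 shared, PBMC 508 and 2447, and cell type differences 7 and 82.

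With the replicate block pauciarticular neutrophils had 5, shared neutrophils 3, and cell type differences 137 and 15, while polyarticular neutrophils had 539 and PBMC 1148, 572 and 369 shared. With the replicate block, the PBMC polyarticular minus pauciarticular values that turned were -0.062 for the oxidative phosphorylation list.

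Without the array that stood apart PBMC counts were 2035, 2193 and 1132 shared, and cell type differences 343 and 57. With spike-in class as a block neutrophils had 15, 0 (284 at an unadjusted p under 0.05 in limma) and 0 shared, PBMC 390, 0 (1378) and 0 shared, and cell type differences 1 and 0 (266). Classes without controls give no direct comparison with controls, so these blocked counts also rest on fewer arrays. With the coarser classes pauciarticular neutrophils had 0 (349 in limma at an unadjusted p under 0.05), 0 were shared, and cell type differences were 127 and 0 (675). PBMC form 1 coarse class, so that fit was not run there. On arrays of the controls' classes alone neutrophils had 1, 0 (139 in limma at an unadjusted p under 0.05) and 0 shared, PBMC 0 (2561), 56 and 0 shared, and the polyarticular cell type difference 1. With the ACTB covariate neutrophils had 844, 321 and 217 shared, PBMC 0 (1947 in limma at an unadjusted p under 0.05), 146 and 0 shared, and cell type differences 13 and 3. Without the controls of high ACTB difference neutrophils had 1111, 277 and 219 shared, PBMC 417 and 1993, and cell type differences 202 and 16.

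The values below are log2 differences, or list medians, of results whose direction turned. A list is counted by the direction of its test, so a median may keep its sign, as at 0.084 for erythroid markers. With the mean of a gene's probe sets, the neutrophil pauciarticular minus control values that turned were -0.012 for BPTF. With array weights, the PBMC polyarticular minus pauciarticular values that turned were 0.021 for the oxidative phosphorylation list, 0.036 for HLA-DPA1, 0.032 for ATP5PO and 0.044 for ATP5F1A. Without the array that stood apart, the PBMC polyarticular minus pauciarticular values that turned were 0.013 for the oxidative phosphorylation list, 0.036 for HLA-DPA1, 0.018 for ATP5PO and 0.053 for ATP5F1A.

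Blocked by class, the neutrophil polyarticular minus control values that turned were -0.18 for HBD and -0.10 for TRIM58. Blocked by class, the neutrophil pauciarticular minus control values that turned were -0.28 for the type I interferon response list, -0.22 for the B cell markers list, -0.088 for OAS2, -0.33 for OAS3, -0.72 for OAS1, -0.0018 for USP18, -0.11 for HLA-DPB1 and -0.79 for MS4A1. They were also -0.21 for FCRL2, -0.37 for TCL1A, -0.0011 for TRIM58 and -0.018 for HBD. Blocked by class, the PBMC pauciarticular minus control values that turned were 0.079 for LCORL. Blocked by class, the PBMC polyarticular minus pauciarticular values that turned were -0.0049 for the oxidative phosphorylation list, 0.18 for HLA-DPA1, 0.018 for ATP5PO, 0.028 for ATP5F1A and -0.020 for HCAR3.

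With the coarser classes as a block, the neutrophil pauciarticular minus control values that turned were -0.42 for the type I interferon response list, -0.16 for the B cell markers list, -0.22 for OAS2, -0.38 for OAS3, -0.75 for OAS1, -0.091 for USP18, -0.49 for MS4A1 and -0.084 for FCRL2. They were also -0.22 for TCL1A.

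In the controls' classes alone, the neutrophil polyarticular minus control values that turned were -0.11 for HBD and -0.020 for TRIM58. In the controls' classes alone, the neutrophil pauciarticular minus control values that turned were -0.46 for the type I interferon response list, -0.096 for the ribosomal proteins list, -0.16 for the T cell markers list, -0.24 for the B cell markers list, -0.19 for the monocyte markers list, -0.15 for the erythroid markers list, 0.11 for FCHSD1 and 0.045 for MAP2K2. They were also 0.087 for PHKG2, -0.77 for OAS2, -0.61 for OAS3, -1.07 for OAS1, -0.18 for USP18, -0.40 for HLA-DPB1, -0.11 for RPL22 and -0.092 for RPS23. They were also -0.19 for RPS21, -0.19 for RPS12, -0.075 for CD3G, -0.44 for CCR7, -0.53 for LEF1, -1.04 for MS4A1, -0.21 for FCRL2 and -0.45 for TCL1A. They were also -0.21 for CCR2, -0.32 for CD36, -0.27 for TUBB1, -0.28 for SPARC, -0.21 for TRIM58, -0.18 for HBD and -0.036 for HBM. In the controls' classes alone, the PBMC polyarticular minus control values that turned were -0.089 for DEFA4. In the controls' classes alone, the PBMC pauciarticular minus control values that turned were 0.050 for LCORL. In the controls' classes alone, the PBMC polyarticular minus pauciarticular values that turned were 0.024 for the oxidative phosphorylation list, 0.094 for the NK and cytotoxic cell markers list, 0.084 for the erythroid markers list, 0.48 for HLA-DQA1, 0.011 for HLA-DRA, 0.71 for HLA-DPA1, 0.017 for RPS28 and 0.0013 for ATP5PO. They were also 0.066 for COX7B, 0.10 for XCL1, 0.16 for GNLY, 0.25 for NKG7, -0.12 for EBF1, 0.071 for IL3RA and 0.16 for LILRA4.

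With the ACTB covariate, the PBMC polyarticular minus control values that turned were -0.0054 for BLK. With the ACTB covariate, the PBMC polyarticular minus pauciarticular values that turned were 0.012 for the oxidative phosphorylation list, 0.038 for HLA-DPA1, 0.017 for ATP5PO and 0.053 for ATP5F1A.

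Without the controls of high ACTB difference, the PBMC polyarticular minus control values that turned were -0.063 for the B cell markers list, -0.015 for CD79A and -0.16 for BLK. Without the controls of high ACTB difference, the PBMC polyarticular minus pauciarticular values that turned were 0.013 for the oxidative phosphorylation list, 0.036 for HLA-DPA1, 0.018 for ATP5PO and 0.053 for ATP5F1A.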

Other observations

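Of the 35 lists, 17 were called in no comparison. In PBMC 3 of 18 helper and regulatory T cell genes fell in polyarticular disease, and 4 when adjusted over the list alone (limma, median -0.14), and the median in pauciarticular disease was -0.17. Among inflammatory lists, NF-kB and TNF response genes had medians of 0.078 and -0.051 in polyarticular and pauciarticular neutrophils and 0.079 and 0.15 in PBMC, toll-like receptor genes -0.031, -0.090, -0.027 and 0.14, inflammasome genes 0.0050, -0.094, -0.030 and -0.012, and immediate early genes -0.038, -0.060, -0.13 and 0.12 in the same order. Respiratory burst oxidase genes stood at -0.094, -0.15, -0.041 and 0.21, Fc and complement receptors at 0.077, -0.043, -0.060 and 0.28, S100 genes, which encode calcium-binding alarmins, at -0.0018, -0.13, -0.15 and 0.16, and chemokine genes at -0.045, 0.018, 0.013 and 0.15.

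In the same order, MHC class I genes stood at -0.031, -0.080, -0.21 and 0.0043, glucocorticoid response genes at 0.0072, -0.081, -0.15 and -0.040, folate and one-carbon genes, on which methotrexate acts, at 0.13, 0.11, -0.024 and -0.077, and heat shock genes at 0.19, 0.16, -0.17 and -0.13. Hypoxia and glycolysis genes stood at -0.0053, -0.080, 0.028 and 0.12, apoptosis genes at -0.094, -0.13, -0.11 and -0.063, plasma cell markers at 0.15, 0.17, 0.075 and -0.030, and eosinophil markers at -0.31, -0.15, 0.030 and 0.21. The lowest camera adjusted p among these, against controls, was 0.0775, for the folate genes in polyarticular neutrophils.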
